A study of Mus musculus with 6 samples.

How the data were processed

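RNA was extracted from the cerebellum of 3 wild-type and 3 Sp4 hypomorphic male mice, cleaned and treated with DNase, and checked on a Bioanalyser, and biotin-labelled complementary RNA was read on Illumina bead arrays, per the labels' protocols. The design describes 3 pairs of littermates, and the labels give each array a genotype and a number from 1 to 3 without saying that the number marks the pair. BeadStudio is named in the submitters' processing notes. Its version, the background method and any genome build are not given in the sources used here.

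The authors deposited a table of non-normalized intensity values with a detection p-value for each probe and array. The intensity values were on a linear scale and already background-subtracted, since they reached -42.8 on hypomorph 3 and their distributions differed between arrays. Detection p-values moved in steps of 1 in 936, and no control probes were used here. A second table of processed values deposited by the authors held intensity on a linear scale, with medians between 161.3 and 161.5. Within each array its ranks equalled those of the non-normalized table (rank correlation 1), and its values lay a median of 140.6 to 142.8 above. Sorted values of each array differed from those of hypomorph 1 by at most 1.71. The values therefore appear to have been quantile-normalized and shifted upward, which is an inference that no header states. All columns matched a sample label.

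Background correction, quantile normalization and a log2 transform with an offset of 16 were made with the neqc function of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values. Normalization makes the distributions equal, so a shift of most transcripts in one direction would not be seen, and the offset makes folds of dim probes smaller. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept. Percentages of probes above background lay between 41.2 and 44.5 on the 6 arrays. The precision rests on 3 arrays per group. Gene names came from the platform annotation: 34885 probes had 1 gene symbol, 18 had several and 10378 had none. Symbols were checked against the gene table of assembly GRCm38.p6, which altered 0 of them. Of the tested probes, 2778 were left unnamed, and they stayed in the tests.

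Each probe was tested with a linear model and moderated variances in limma (lmFit and eBayes), hypomorph minus wild type, without a block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each animal was taken as 1 replicate. For a probe that was not above background on any array of a group, the fold was given as a bound. A total of 33 gene lists were fixed beforehand from textbook knowledge, and 32 with at least 5 measured genes were tested with camera of limma (two-sided, preset correlation of 0.01), using the brightest probe of each gene, with adjustment over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way without comparing them with other genes, called 0 lists each. The lists hold 791 different genes, 553 of them measured. Some lists share genes: 9 of 25 granule cell markers, 13 of 32 Purkinje cell markers and 4 of 36 oligodendrocyte and myelin genes are also in another list. The brightest Fchsd1 probe, which stands for the gene among the genes linked to Sp4, is the one with the smaller difference.

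The genes named were chosen by a rule: Sp4, up to 12 genes per direction past the threshold that went the same way in all same-numbered pairs, filled up to 6 with the smallest unadjusted p and a fold of at least 1.2 where fewer passed, Fchsd1 and Grin1, and the 3 members with the smallest p in each list that passed or that had a member passing over the list alone. Riken and predicted genes counted only if no other gene was left. Other members are named as examples chosen after their values were seen. The main design, the tests across probes and lists, the lists, this rule and the alternatives were fixed before the data were examined, except 1 alternative that left out both arrays numbered 2. Some tests of explanations, and some of their bounds, were chosen or revised after values were seen. The alternatives were a replicate block, no background correction, median scaling, an offset of 50, the authors' processed values, no filter, a stricter filter, a variance trend with robust moderation, array weights, each array left out in turn, a test with unequal variances, unadjusted thresholds, other set tests and the mean over probes.

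The test was checked on simulated data made from the spread of these arrays, in 10 sets of 19515 probes with 200 changed in each. At the same threshold it recovered 3% of probes changed 1.5-fold, 53% of those changed 2-fold, 97.6% of those changed 4-fold and 99.4% of those changed 8-fold, with 60 false calls beside 1265 true ones over all sets. These shares hold for sets with many changed probes, where the adjustment accepts larger unadjusted p-values. They overstate the recovery where few probes change: on the real arrays Gcnt1 did not pass at 7.05-fold (unadjusted p = 3.82e-06 in limma). The set test found 20 of 20 simulated lists of 30 genes shifted by -0.25 on the log2 scale and called 0 of 20 lists without a shift. The simulated genes varied independently of each other, so this says nothing about false calls among lists whose genes vary together: the estimated correlation was 0.678 in the myelin list and 0.134 in the cholesterol list, and on the real arrays splits that mix the genotypes gave up to 9 lists. Figures were drawn with matplotlib 3.10.9.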

Results

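Gene expression was measured in the cerebellum of male mice at postnatal day 21, in 3 wild-type animals and 3 littermates that were hypomorphic for Sp4, a zinc-finger transcription factor of the Sp family that binds GC-rich promoter elements. A hypomorph carries an allele that lowers the amount or function of a gene product without necessarily removing it, and the mice came from a Black Swiss by CD1 cross. Labelled RNA of each animal was read on an Illumina bead array with 45281 probes. Between 18656 probes (hypomorph 1) and 20135 probes (hypomorph 2) gave a signal above background on an array, and 19515 probes that did so on at least 3 of the 6 arrays were tested, of which 16737 carried the name of 1 gene (10764 genes). The number of arrays limits the precision of every value below, and a permutation of single values between groups of 3 cannot give an exact two-sided p under 0.1.

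The comparison asks which transcripts depend on Sp4 in the cerebellum. Sp4 itself was lower in the hypomorph on both of its tested probes. Probe ILMN_1259753 averaged 7.34 ± 0.48 (log2 intensity, SD, n = 3) in wild type and 6.04 ± 0.26 in the hypomorph, a log2 difference of -1.30 with an SE of 0.26, or 2.47-fold. Probe ILMN_1253376 averaged 6.26 ± 0.45 in wild type and was not above background on any hypomorph array, so that its difference was at least 1.5-fold. For such probes the fold is a bound, taken against the higher of the probe's own signal and the lowest signal above background on each array, and it holds for this normalization only. It bounds the difference between the group means of these arrays and leaves out the spread between animals, so it is not a confidence limit. The 2 groups did not overlap on either probe, so each hypomorph array necessarily also lay below the wild-type array of the same number. Neither probe passed limma's test after Benjamini-Hochberg adjustment over all tested probes, with an unadjusted p of 0.00136 and an adjusted p of 0.355 for the first and 0.00105 and 0.354 for the second. With the values processed by the authors the log2 difference of the first was -0.60. Whether the probes lie in the part of the transcript altered in the hypomorph is not given in the sources used here. A probe outside it can read the level of the transcript but not the altered part itself.

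Among all tested probes, 0 reached an adjusted p under 0.05 in limma, and the lowest adjusted p was 0.0745. An unadjusted p under 0.05 was found for 1036 probes, 485 higher and 551 lower in the hypomorph, where chance alone gives 975.75. An unadjusted p under 0.001 was found for 54 probes, 24 higher and 30 lower. A test per probe without shared or equal variances also gave 0 probes after adjustment and 802 at an unadjusted p under 0.05. The groups did not overlap at 2053 probes, or 10.5%, where chance gives 10%. In 67.2% of probes the difference lay within 0.2 on the log2 scale. The count of 0 changed with the processing: 13 probes passed when arrays were weighted by their quality, 8 with the values processed by the authors and 8 with a variance that followed intensity. Leaving out hypomorph 2 gave 1 probe (Gcnt1), and leaving out wild type 3 gave 2 probes (Pdrg1 and Mkks, named here after their values were seen).

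No gene passed the threshold, so the genes that follow are those with the smallest unadjusted p in each direction, without Riken and predicted genes (which left out 9430038I01Rik), and they are given as values that did not pass. Lower in the hypomorph were Gcnt1, a Golgi enzyme that branches O-linked glycans, Tmem159, a protein of lipid droplet assembly, Tspan17, a tetraspanin, Comp, an extracellular matrix protein, Smim20, a small mitochondrial membrane protein, and Cited4, a transcriptional co-activator. Gcnt1 had the largest of these differences, with a mean of 9.19 ± 0.24 (SD, n = 3) in wild type and 6.37 ± 0.40 in the hypomorph, a log2 difference of -2.82 with an SE of 0.23, or 7.05-fold. Its second tested probe was lower by a similar amount, with a log2 difference of -2.63 (SE 0.28). Gcnt1 had the lowest adjusted p, 0.0745, and Tmem159 and Tspan17 followed with 0.0997 each. The log2 difference of Tspan17 was -1.30, -1.46 and -1.60 on its 3 tested probes, that of Tmem159 was -1.31 and -0.88 on 2, and that of Smim20 was -1.73 and -1.07 on 2. Cited4 had a log2 difference of -1.26 (SE 0.17). Comp was not above background on any hypomorph array and was at least 1.62-fold lower there. With the values processed by the authors the log2 differences were smaller, at -1.755 for Gcnt1, -0.89 for Tmem159, -0.81 for Smim20 and -0.73 for Cited4. Gcnt1, Tmem159 and Tspan17 each passed the threshold in 5 of 8 other processings of the 6 arrays, all fitted without a block. Among these processings, the stricter filter removed the leading probe of Gcnt1.

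Higher in the hypomorph, again without passing, were Pcdh9 and Pcdh20, protocadherins of cell adhesion, Cdk5rap1, an enzyme that modifies mitochondrial transfer RNA, Rassf7, a protein with a Ras association domain, Btg4, a member of an antiproliferative family, and Plekhf2, an endosomal protein. The lowest adjusted p among them was 0.112. Btg4 averaged 6.40 ± 0.47 (SD, n = 3) in wild type and 8.38 ± 0.12 in the hypomorph, a log2 difference of 1.98 with an SE of 0.24, or 3.96-fold. It passed the threshold in 4 of 8 other processings, of which the stricter filter removed its only tested probe. Cdk5rap1 was higher on all 3 of its tested probes, with log2 differences of 1.64, 1.16 and 0.98. Pcdh20 was higher by 1.00 and 0.86 on its 2 tested probes, and Rassf7 by 1.23 on one probe and at least 1.49-fold on the other, which was not above background on any wild-type array. Plekhf2 was at least 2.62-fold higher on its first probe for the same reason and differed by 0.67 on its second. The probes of Pcdh9 disagreed: one differed by 2.25 (SE 0.27), others by 0.70 and 0.66, and the brightest by -0.05 (SE 0.13). With the authors' values the leading probes differed less, by 1.12 for Btg4, 0.68 for Cdk5rap1, 0.57 for Rassf7 and 1.04 for Pcdh9.

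**Figure D1:**
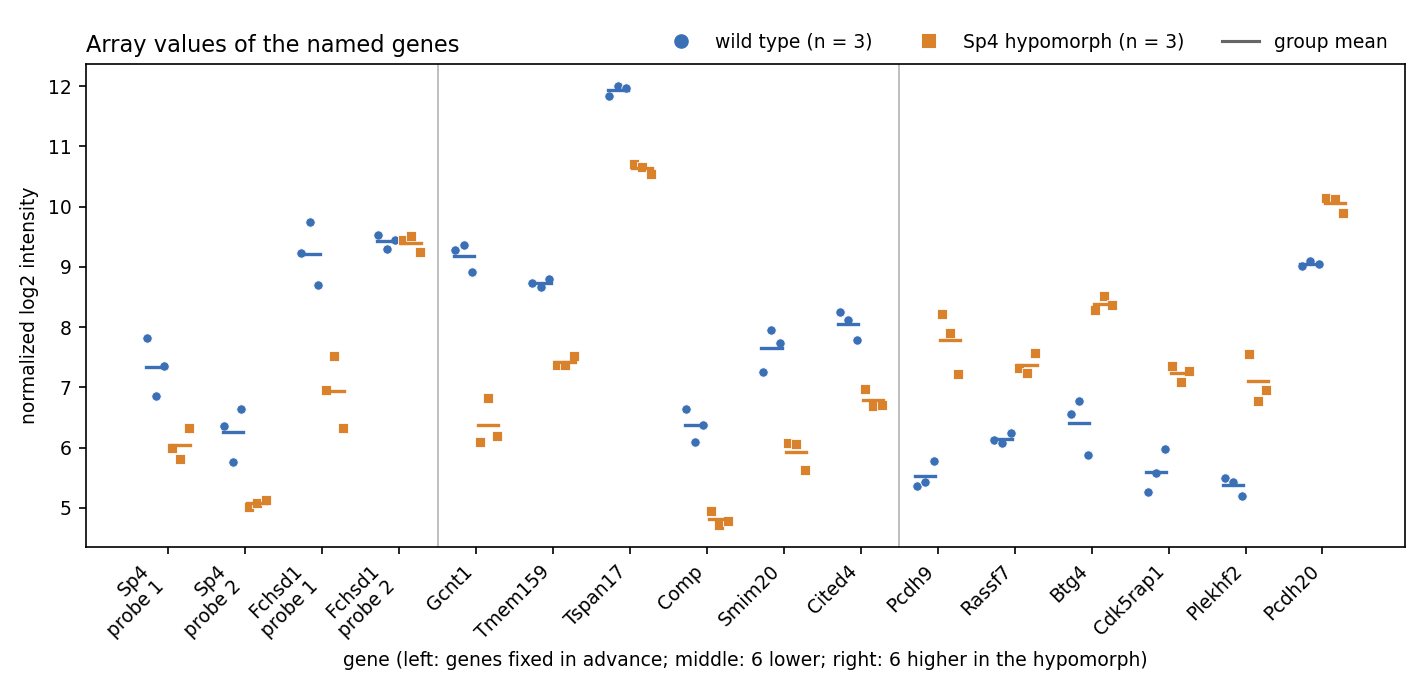
Normalized log2 intensity (vertical axis) of each array for Sp4, Fchsd1 and, Riken and predicted genes left out, the 6 genes with the smallest p in each direction (horizontal axis), with circles for 3 wild-type arrays, squares for 3 Sp4 hypomorph arrays and bars for group means. Gcnt1 averaged 9.19 in wild type and 6.37 in the hypomorph, while the groups overlapped on the second probe of Fchsd1.

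Fchsd1, an adaptor protein of membrane shaping, and Grin1, the obligatory subunit of NMDA-type glutamate receptors, were chosen in advance because earlier work on Sp4 had named them. Fchsd1 differed between its probes. Probe ILMN_2741189 averaged 9.22 ± 0.52 (SD, n = 3) in wild type and 6.93 ± 0.60 in the hypomorph, a log2 difference of -2.28 with an SE of 0.36, and did not pass (unadjusted p = 0.000311, adjusted p = 0.225 in limma); the authors' values gave -1.525. Probe ILMN_1227065 averaged 9.42 and 9.40, a log2 difference of -0.02 with an SE of 0.14, and this sign turned to 0.06 without hypomorph 3 and to 0.03 without wild type 1. Another probe was not above background on any array. Grin1 was not analysed here. Of 10 measured genes linked to Sp4 in earlier work, 3 had higher and 7 lower values. None passed over all probes or adjusted over the list alone, and the list did not pass the set test (camera adjusted p = 0.904). Fchsd1 stood in this list by its brightest probe, ILMN_1227065, so these results leave out the difference of -2.28 on ILMN_2741189. The mitochondrial transcription factor Tfam had a log2 difference of -0.28 (SE 0.13) and the glucose transporter Slc2a3 one of 0.19 (SE 0.14).

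Oligodendrocyte and myelin genes were mostly lower in the hypomorph: 26 of 29 measured members had lower values, with a median log2 difference of -0.23 (camera adjusted p = 0.00111 over 32 lists). The same test also gave this list small p-values in several splits of the arrays that mix the genotypes, which are given further below. With an estimated correlation, which was 0.678 between members, the list did not pass (adjusted p = 0.936). No member passed over all probes or adjusted over the list alone. The members with the smallest p were Ninj2, an adhesion molecule, with a log2 difference of -0.79 (SE 0.24), Gjb1, a gap junction protein of myelinating cells, with -0.80 (SE 0.29), and Cnp, a myelin enzyme, with -0.27 (SE 0.13). A second tested probe of Cnp differed by -0.16 (SE 0.15). With the authors' values Ninj2 differed by -0.36 and Gjb1 by -0.32. Mbp, which encodes myelin basic protein, differed by -0.02 (SE 0.14), and Nkx6-2, a transcription factor of oligodendrocytes, by 0.35 (SE 0.38). Oligodendrocyte precursor markers had lower values in 9 of 14 and did not pass (adjusted p = 0.380). The myelin call was lost without hypomorph 2 (adjusted p = 0.0740), without hypomorph 3 (0.0593) and without wild type 1 (0.231). The median moved to -0.42 without hypomorph 1 and without wild type 2, and to -0.12 without wild type 1. The means of the list on single arrays overlapped between the groups: wild type 2 (-0.29) lay beside hypomorph 2 (-0.29), and hypomorph 1 (0.16) lay above it.

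Genes of cholesterol synthesis were mostly lower as well: 14 of 17 measured members had lower values, with a median log2 difference of -0.18 (camera adjusted p = 0.0141). With an estimated correlation this list did not pass (adjusted p = 0.936). No member passed over all probes or adjusted over the list alone. Cyp51, a sterol demethylase, differed by -0.56 (SE 0.22), and Lss, the enzyme that closes the sterol rings, by -0.45 (SE 0.21). Insig1, a sterol-responsive regulator of the pathway, differed by -0.48 (SE 0.23), or -0.72 without hypomorph 1 and -0.28 without hypomorph 2. Other tested probes differed less, by -0.16 (SE 0.18) and -0.23 (SE 0.21) for Insig1 and by -0.15 (SE 0.17) for Lss. Ebp, a sterol isomerase, and Stard4, a sterol carrier, had higher values, by 0.14 (SE 0.13) and 0.15 (SE 0.16). The call was lost without hypomorph 2 (adjusted p = 0.168), hypomorph 3 (0.0593), wild type 1 (0.0904) or wild type 3 (0.0643), and the median moved to -0.28 without hypomorph 1. The means of this list on single arrays overlapped too, with hypomorph 1 (0.0864) above wild type 2 (-0.00231).

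**Figure D2:**
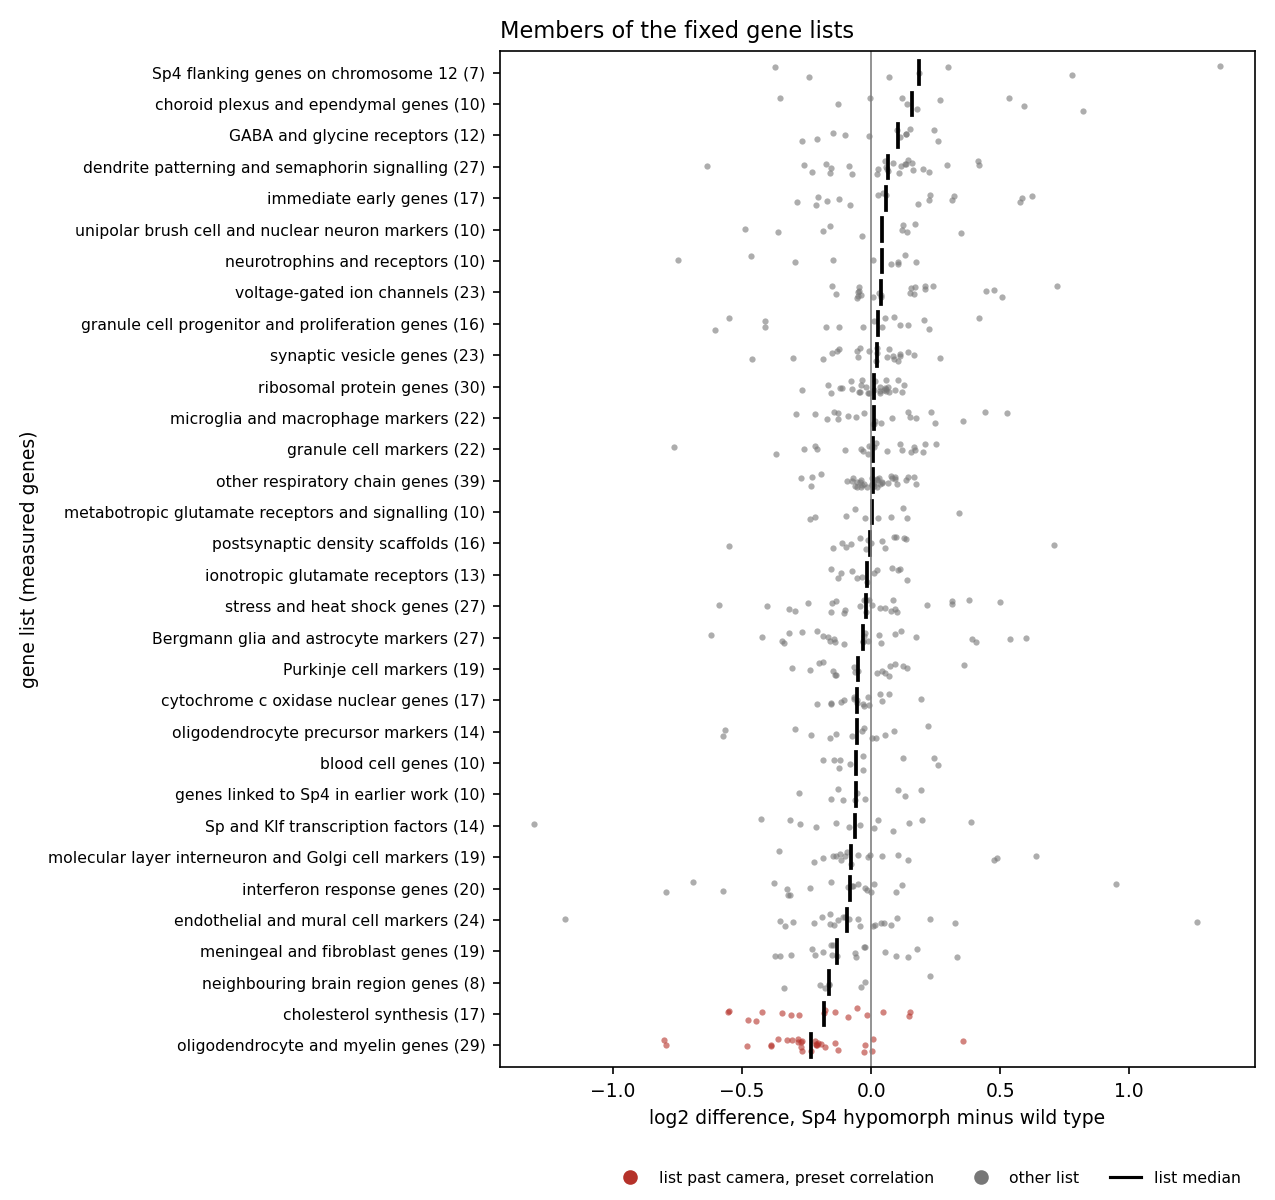
Log2 difference between Sp4 hypomorph and wild type (horizontal axis) of the measured members of 32 gene lists (vertical axis, number of members in parentheses), with a point for each gene and a black line for each list's median. The lists of myelin and cholesterol genes, in red, have medians of -0.23 and -0.18. In the list named for genes flanking Sp4, 4 of 7 lie within 10 Mb of it.

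The other 30 lists did not pass the set test, the lowest adjusted p among them being 0.267, and their medians lay between -0.16 and 0.19. Without wild type 2 the lists that passed numbered 6, without wild type 3 only 1, and without hypomorph 2, hypomorph 3 or wild type 1 there were 0. The glutamate receptors showed small differences: 6 of 13 ionotropic subunits had higher and 7 lower values (adjusted p = 0.966), among them Grin2a at -0.13 (SE 0.33) and Grin2b at -0.16 (SE 0.31), and metabotropic receptors with their signalling partners had 5 of 10 higher (0.904). Of GABA and glycine receptors 7 of 12 were higher (0.694), of synaptic vesicle genes 13 of 23 (0.904), of voltage-gated ion channels 15 of 23 (0.267), and of genes of dendrite patterning and semaphorin signalling 19 of 27 (0.380). Postsynaptic density scaffolds had 8 of 16 higher (0.904), and neurotrophins and their receptors 6 of 10 (0.629). In 5 lists 1 member each passed adjusted over the list alone, though none over all probes. These were Sp4 among the Sp and Klf factors, the scaffold protein Shank1 (at least 1.15-fold higher), the neurotrophic factor receptor Ret (log2 difference -0.75, SE 0.16), the granule cell marker Fstl5 (-0.76, SE 0.14) and the endothelial transporter Slco1a4 (1.26, SE 0.26). With the authors' values Fstl5 differed by -0.34 and Slco1a4 by 0.57. Beside Shank1, Cbln4 differed by -0.55 (SE 0.28) and Dlgap1 by 0.13 (SE 0.16), and beside Ret, Gfra1 differed by -0.30 (SE 0.14) and Gdnf by -0.47 (SE 0.36). These values were unsteady: Gdnf stood at -0.09 without hypomorph 3 and -0.19 without wild type 2, and Dlgap1 at 0.02 without wild type 3 and 0.26 without wild type 2, while the authors' values gave -0.19 for Gdnf, -0.10 for Gfra1 and -0.20 for Cbln4. A second tested probe of Ret differed by -0.23 (SE 0.19), and other tested probes of Dlgap1 ran from -0.19 (SE 0.17) to 0.26 (SE 0.18).

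The Sp and Klf transcription factors had higher values in 6 of 14 (camera adjusted p = 0.656). Klf16 stood at -0.43 (SE 0.16) and Klf6 at 0.39 (SE 0.22), which was 0.15 without hypomorph 2. The authors' values gave -0.28 for Klf16. Second tested probes differed by -0.16 (SE 0.28) for Klf16 and 0.19 (SE 0.17) for Klf6. A list fixed beforehand as genes around Sp4 on mouse chromosome 12 had higher values in 5 of 7 (0.694), but Twistnb, Hdac9 and Twist1, 3 of the 7, lie more than 10 Mb from Sp4 in assembly GRCm38.p6, so only 4 are neighbours. Rapgef5, the measured gene next to Sp4, differed by 1.35 (SE 0.45), a value that did not pass (adjusted p = 0.820). The remaining cell type lists did not pass. Higher values were found for 12 of 22 granule cell markers (0.966), 9 of 16 progenitor and proliferation genes (0.694), 9 of 19 Purkinje cell markers (0.904), 6 of 19 markers of molecular layer interneurons and Golgi cells (0.966) and 5 of 10 of unipolar brush cells and nuclear neurons (0.966). Among glia, vessels and coverings of the brain, values were higher for 9 of 27 Bergmann glia and astrocyte markers (0.904), 13 of 22 microglia and macrophage markers (0.629), 9 of 24 endothelial and mural markers (0.656), 5 of 19 meningeal and fibroblast genes (0.656), 7 of 10 choroid plexus and ependymal genes (0.380) and 3 of 10 blood cell genes (0.936). Beside Fstl5, Kcnd2 differed by 0.21 (SE 0.16) and Fat2 by 0.25 (SE 0.21); without 1 array Kcnd2 ran from 0.10 to 0.33 (without wild type 2 and wild type 1) and Fat2 from 0.13 to 0.45 (without wild type 3 and wild type 2). A second tested probe of Kcnd2 differed by 0.32 (SE 0.30). Beside Slco1a4, Slco1c1 differed by -0.35 (SE 0.14) and Eng by -0.33 (SE 0.15).

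Housekeeping and response genes did not pass either. Higher values were found for 4 of 17 nuclear genes of cytochrome c oxidase (camera adjusted p = 0.694), 23 of 39 other respiratory chain genes (0.936), 16 of 30 ribosomal protein genes (0.966), 11 of 17 immediate early genes (0.380), 4 of 20 interferon response genes (0.287), 12 of 27 stress and heat shock genes (0.936) and 1 of 8 genes of neighbouring brain regions (0.380). In 10 of the lists that did not pass, the median, the mean and the set test differed in sign: ionotropic glutamate receptors, postsynaptic scaffolds, synaptic vesicle genes, neurotrophins, other respiratory chain genes, ribosomal protein genes, granule cell markers, progenitor and proliferation genes, molecular layer interneuron markers, and unipolar brush cell and nuclear neuron markers. The sex given in the labels was checked with Eif2s3y, Kdm5d and Uty, Y-linked genes that were above background on all 6 arrays. This list had 3 measured genes and was not tested.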

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

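Of the tests here, leaving out both arrays numbered 2 was chosen only after the result was seen. Against 0 probes past the threshold, 2 passed with the replicate block, 1 with no background correction, 5 with an offset of 50, 8 with the authors' processed values, 2 with the stricter filter, 8 with a variance trend and robust moderation, and 13 with array weights; without 1 array the count ran from 0 to 2. Unadjusted p under 0.05 gave 1036 probes, and 439 with a fold of at least 1.5. The gene lists past the set test numbered 2, 0 with an estimated correlation, 0 with fry, and 0 to 6 without 1 array. The adjusted p of the cholesterol list was 0.936 with an estimated correlation, 0.910 with fry, 0.0667 without both arrays numbered 2, and 0.000762 to 0.168 without 1 array; that of the myelin list was 0.936, 0.922, 7.81e-08 and 2.80e-09 to 0.231. Their cause was not tested, beyond fewer arrays where arrays were left out. Sp4 stayed lower wherever it was tested, by -1.53 to -0.60 on probe ILMN_1259753 and without a size on ILMN_1253376; the stricter filter removed both, and the second was also untested without a wild-type array. Of the named genes, values reversed only for probe ILMN_1227065 of Fchsd1, at 0.06 without hypomorph 3 and 0.03 without wild type 1, in a range without 1 array of -0.09019 to 0.0551; 504 other values kept direction and side of the threshold and 28 passed it. Median scaling moved the median of all probes by 0.04 at most. The 2 probes of the replicate block were Fchsd1 ILMN_2741189 and Gcnt1 (adjusted p = 0.0394 each; over its alternatives Gcnt1 ran from 0.00502 to 0.357). The deviations of same-numbered arrays from their group means correlated by 0.44, 0.40 and 0.06 across probes, each array correlating best with its own number, which is a hint from the data and not the design, so the numbers were not taken as pairs. A slide block was not run because the files give no slide. Signal over background limits Sp4, Comp, Plekhf2, Rassf7 and Shank1 to bounds on a probe each.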

Other observations

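The tests chosen only after the result was seen were those on the other probes of the leading genes and on genes near Sp4 in other splits of the arrays, and the bounds for haplotype blocks and for single arrays were revised after their values were known. Arrays differed in marker genes in ways that did not follow the genotype. On both arrays numbered 2 the list means, relative to each gene's mean over the 6 arrays, were low for oligodendrocyte and myelin genes (-0.29 in hypomorph 2 and -0.29 in wild type 2), for meningeal and fibroblast genes (-0.40 and -0.31) and for Bergmann glia and astrocyte markers (-0.23 and -0.18), and granule cell markers were at 0.06 and 0.29. The choroid plexus and ependymal list stood at -0.58 on wild type 2 and between 0.02 and 0.24 on the other arrays. The first principal component held 40.0% of the variance, with hypomorph 2 and wild type 2 at one end and wild type 1 and hypomorph 1 at the other. The second held 20.3% and parted the genotypes. On it hypomorphs 1 to 3 stood at 18.1, 22.6 and 5.93, and wild types 1 to 3 at -4.97, -30.8 and -10.8. Chance alone parts 2 groups of 3 arrays on a given component in 10% of cases, and several components were examined. This parting is therefore no evidence for an effect of the genotype.

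Pdrg1 and Mkks, named after their values were seen, split the wild-type animals. Pdrg1 stood at 4.71 and 4.93 (log2) on wild type 1 and wild type 2 and at 10.1 on wild type 3, close to the hypomorphs at 10.2, 10.3 and 10.2. Probe ILMN_2814350 of Mkks stood at 4.96, 4.77 and 8.11 on the wild-type arrays and at 7.77, 7.99 and 8.05 on the hypomorph arrays, while its other probe lay between 10.6 and 11.2 on all 6. Both passed the threshold without wild type 3, the only wild-type array on which these probes were above background, so no size is given. The non-coding RNA Rian, chosen likewise, stood at 8.84 on hypomorph 2 and between 5.82 and 6.20 on the other arrays, and the pericyte marker Rgs5, from the endothelial and mural list, at 7.5 on hypomorph 1 and between 9.27 and 10.3 elsewhere.

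The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1036 probes at an unadjusted p under 0.05 and the highest other split 3193, and 3 of the 10 splits, the real one included, gave as many as the real one. At an unadjusted p under 0.001 the real split gave 54 probes and the highest other 97. At an adjusted p under 0.05 the real split gave 0 probes, and mixed splits gave up to 5. For gene lists past the set test the real split gave 2 and the highest other 9, and 8 of the 10 splits gave as many. The split with 3193 probes set hypomorph 1, wild type 1 and wild type 3 against the rest, which points to a structure of the arrays that the genotype does not describe. It kept both arrays numbered 1 on one side and both numbered 2 on the other. Among splits that part all same-numbered arrays, the real one gave more probes at an unadjusted p under 0.05, 1036 against 445, 503 and 356. At 0.001 it gave 54 against 10, 3 and 0. It did not lead in probes past the adjusted threshold (0 against 4, 0 and 0) or in lists (2 against 0, 5 and 2). No label ties a number to a litter, and so few splits cannot give a small share.

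Where genes with the smallest p had other tested probes, these mostly had the same sign. Of 39 genes with an unadjusted p under 0.001, 22 had other tested probes. In 19 of them, or 86.4%, these shared the sign of the leading probe (one-sided exact binomial p = 0.000428 against even odds of either sign). The share was 61.2% over all 4091 genes with several tested probes, and the excess over that share was not tested. The agreement in sign argues against a fault of single probes as the account of these genes as a set. Only the sign was counted, so genes whose probes differed in size are among the 19, such as Fchsd1, Pcdh9, Plekhf2, Hcn3 and Tpi1. The other probes had the opposite sign for Esd (log2 differences of 1.31 on the leading probe and -0.31 on average over the others), Cd40 (-0.79 and 0.12) and Pigh (0.88 and -0.22). A sequence variant under a probe or a different transcript end stays open for genes of both kinds. The share of other probes also cannot separate the Sp4 genotype from other genetic differences between the animals.

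Genes with a small p lay near each other on the chromosomes. Among 149 genes with an unadjusted p under 0.01, 104 pairs lay within 5 Mb by the gene order of assembly GRCm38.p6, against 65.8 on average when the p values were permuted over genes (permutation p = 0.0025); overlapping neighbours do not account for it, since pairs at least 100 kb apart gave p = 0.0035, nor do genes within 10 Mb of Sp4, without which p was 0.0025. A candidate explanation is that blocks of DNA inherited together in the outbred cross differed between the 2 groups of 3 animals: 2 of the 9 splits that mix the genotypes also had an excess, with 76 pairs against 17.0 permuted (p = 5e-04, the smallest the permutations can give) and 13 against 4.38 (p = 0.0035), while the mixed splits with the most such genes, 483 and 139, had none (p = 0.956 and 0.303). The bound of 5 splits set beforehand for this was wrong by the design, because a block gives an excess only in the splits that part its carriers from the other animals, so haplotype blocks and effects of Sp4 cannot be told apart here. This limit falls on the genes named above, of which Tspan17, Comp, Cited4, Rassf7, Cdk5rap1, Pcdh20, Ret, Shank1 and Fstl5 are each in such a pair. A gene outside such pairs is not freed from it. Pairs were formed from the brightest probe of each gene. Fchsd1 and Pcdh9 could therefore not enter one, with unadjusted p-values of 0.877 and 0.742 in limma on that probe. For DNA carried along with the targeted allele, 8 of 53 genes within 10 Mb of Sp4 (15.1%) had an unadjusted p under 0.05. Among other genes 5.17% did (Fisher's exact two-sided p = 0.00582). Of the 9 mixed splits 1 showed such an excess too, which keeps this explanation open. In chromosome order Sp4 was gene 54 of the 54 measured in this window. Of the 8 genes, Cyp46a1, Eml1, Evl and Slc25a47 stood at 1, 2, 3 and 5, far from Sp4. Rd3l, Nudt14, Tmem121 and Rapgef5 stood at 34, 42, 48 and 53. The excess therefore rests partly on genes at the far edge of the window.

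Oligodendrocyte and myelin genes had lower values in the hypomorph. Leaving out 1 array moved the list's median from -0.23 to between -0.42 and -0.122, the last without wild type 1. That value lies within its bootstrap SE of 0.0176 from the bound of -0.116 that marks 50% of the shift. The SE came from resampling the genes of the list as if independent, though their estimated correlation was 0.678. It therefore leaves out the spread between animals. Whether 1 array carries the shift is undecided. A smaller share of oligodendrocytes in the tissue taken may account for it: 0 of 7 core myelin genes had a 95% interval that excluded the list's median, but all 7 intervals also held 0, so the test could not have excluded it. An effect of Sp4 on oligodendrocytes, uneven dissection and the array structure above therefore stay open. A chance difference between 3 and 3 animals stays open too. The list did not pass camera with an estimated correlation (adjusted p = 0.936) or fry (adjusted p = 0.922). The set test's p for this list was smaller than the real one, 3.48e-05, in 2 mixed splits (5.86e-15 and 1.64e-06). In further mixed splits it was 9.95e-05, 0.000966, 0.0012 and 0.00579, and in the remaining ones 0.0687, 0.084 and 0.195. A small p of this test for this list therefore also arises where the split does not follow the genotype.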
